A study of Mus musculus with 16 samples.

How the data were processed

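Tumour RNA was extracted with a Qiagen RNeasy kit, made into TruSeq mRNA libraries and sequenced on an Illumina HiSeq instrument as 50 bp single reads, per the labels' protocols. Per the submitters' processing notes, STAR 2.7, HTSeq and DESeq2 were used with the mm10 genome; the role and settings of each are not given in the sources used here, nor is the strand setting. The 1 deposited table holds, per the file headers, a value per gene for each of 16 libraries, group means, and the authors' comparison. The 16 deposited library columns hold a non-negative signal, called normalized counts here, and no header says how the authors made it. From the values, they are read counts divided by 1 size factor per library, since in each library the deposited values are whole multiples of its smallest value above 0 (100% of values within 0.01 reads). The authors' comparison columns hold a log2 fold change with its error, p-value and FDR adjusted p-value, and a Wald score, per the file headers. For 634 genes the authors' overall mean lies below the plain mean of the 16 libraries.

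The table has 23563 lines with values and 1 emptied line. For each Ensembl ID 1 line was kept, which removed 208 lines and left 23355 genes, of which 23322 were found in the reference gene table. Libraries 1 to 9 were taken as H3.3WT and 10 to 16 as H3.3K27M, because the file headers average these sets and only the labels' groups of 9 and 7 have those sizes. Libraries are named by their number in the table. The design text calls the tumours independent, and p-values measure the spread between the libraries. Of the 16 labels, 10 share a middle code with another, and no fit by that code was possible as no library can be tied to a label.

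The planned test was edgeR's quasi-likelihood test on counts. As the deposited values are normalized, the test used was limma 3.58.1 with a mean-variance trend on log2(value + 1), for 15007 genes with at least 10 normalized counts in at least 7 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are H3.3K27M minus H3.3WT. Gene lists (44, fixed before the data were examined) were tested with limma's camera at a preset correlation of 0.01 where at least 4 members were measured. The lists of model genes and of sex-linked genes were not tested as lists, and with the mitochondrially encoded genes not analysed here, 41 were tested. Camera with an estimated correlation, fry, and a two-sided exact permutation test of each list's score (the mean log2 value of its members, 11440 assignments) were run as well. List scores were planned on log2 CPM and were computed on log2(value + 1) instead. The named genes were the genes of the model and Xist, the genes with the 10 smallest p-values, and up to 4 members of each list with the smallest p; a further part, the largest changes past the threshold, was empty. Of the genes with the 10 smallest p-values, 1 is not reported here. Exon length and GC content came from the GENCODE M21 annotation of mm10. R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.

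Reads were recovered by dividing each value by the smallest value of its library above 0. A count of 0 allows up to 3 reads, which is 2.42 normalized counts in library 16 and 8.52 in library 8; such limits cover counting error only. Low genes are therefore known least well in library 8.

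The steps were tested on simulated counts for the real genes, with 50 genes changed at each of 4 fold sizes. In the simulated H3.3K27M against H3.3WT comparison over 14948 genes, limma recovered 8% of genes changed 1.5-fold, 54% changed 2-fold, 76% changed 4-fold and 94% changed 8-fold, and called 6 unchanged genes. edgeR recovered 12%, 52%, 76% and 96% and called 5 unchanged genes. DESeq2 recovered 20%, 60%, 84% and 96% and called 22 unchanged genes. A list of 25 genes shifted 1.5-fold had an adjusted camera p of 6.3e-12, and 0 of 40 unshifted random lists passed. Simulated genes vary independently, unlike the genes of a list in tissue.

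Alternatives fixed before the data were examined were TMM and upper quartile scaling, DESeq2's Wald test on the recovered reads, limma voom with quality weights, no filter beyond 1 count, at least 1 CPM in at least 7 libraries, each library left out in turn, and Xist, neuron score or microglia score as a covariate. Added after the data were seen were edgeR's quasi-likelihood test on the recovered reads, pseudocounts of 0.5 and 5, removal of each library's trend on exon length or on GC content, and leaving out libraries 6 and 8 together. Fits that needed the label of each library (a replicate block, and fits by label prefix) or the mitochondrially encoded genes were not run.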

Results

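RNA was sequenced from 16 mouse brain tumours of a model of diffuse midline glioma, a childhood brain cancer in which the histone variant H3.3 often carries methionine in place of lysine 27 (H3.3K27M). Avian RCAS viruses infect only cells that carry their receptor, tv-a, here placed under the Nestin promoter of neural progenitor cells. Viruses carrying PDGF-A, Cre recombinase and either H3.3K27M or the unmutated H3.3 (H3.3WT) were injected on postnatal day 3 into mice with a floxed p53 gene, and tumours were collected at endpoint. The sample labels name 9 H3.3WT and 7 H3.3K27M tumours. The deposited table numbers its libraries 1 to 16 and averages libraries 1 to 9 and 10 to 16 separately. These were taken as the H3.3WT and H3.3K27M groups because the group sizes match in only that way. No library can be tied to a named tumour, and every direction below rests on this assignment. The design text of the series counts 5 tumours with and 3 without H3.3K27M, which differs from the labels. Between 11439144 reads (library 8) and 41730692 reads (library 16) were recovered per library, and every library other than library 8 held at least 30377560. Between 16135 and 17656 genes had a read. Libraries of a group correlated with Pearson r of 0.862 to 0.957 across genes, which are not independent replicates, and no pair was within sampling noise (chi-square per degree of freedom of at least 129).

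The comparison asks what H3.3K27M adds to tumours driven by PDGF-A and p53 loss, so the genes of the model are given first. Pdgfa, the gene of the driving growth factor, averaged 26423 ± 8492 normalized counts (SD, n = 9) in H3.3WT and 25508 ± 14849 (SD, n = 7) in H3.3K27M tumours. Its receptor gene Pdgfra, also a marker of oligodendrocyte progenitors, averaged 94096 ± 50070 and 139883 ± 61642, a log2 fold change of 0.66 ± 0.36 (SE). Pdgfrb, a receptor gene of the same family, averaged 2225 ± 1235 and 1501 ± 590, and the progenitor gene Nes 8869 ± 2867 and 7454 ± 2838. H3f3a, an H3.3 gene, averaged 321 ± 52.1 and 256 ± 44.6, and its sister gene H3f3b 25518 ± 7813 and 18227 ± 6150. Trp53, the p53 gene, averaged 1482 ± 595 and 909 ± 194, and lay below the H3.3WT median in all 7 H3.3K27M tumours. None of these passed limma with Benjamini-Hochberg adjustment: adjusted p was 0.784 for Pdgfa, 0.383 for Pdgfra, 0.597 for Pdgfrb, 0.620 for Nes, 0.370 for H3f3a, 0.313 for H3f3b and 0.266 for Trp53. Gene-level values do not separate the mutant H3.3 transcript from the unmutated one. Xist, expressed in females, exceeded the Y-linked Ddx3y in 6 of 9 H3.3WT and 3 of 7 H3.3K27M libraries, and Xist had an adjusted limma p of 0.710.

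Among single genes, Kmt2d and Kmt2c had the smallest p-values, and both lay higher in H3.3K27M tumours. Kmt2d (mm10, chromosome 15, 98831668 to 98871205) and Kmt2c (chromosome 5, 25271793 to 25498783), which encode histone H3 lysine 4 methyltransferases, averaged 3155 ± 861 and 2641 ± 542 normalized counts (SD, n = 9) in H3.3WT tumours. In H3.3K27M tumours they averaged 5441 ± 757 and 4894 ± 1035 (SD, n = 7). Their log2 fold changes were 0.81 ± 0.15 and 0.89 ± 0.16 (SE). Lig4 (chromosome 8, 9970019 to 9976323), the DNA ligase gene of non-homologous end joining, averaged 413 ± 62.4 and 697 ± 132 in the same order (log2 fold change 0.74 ± 0.16). The ephrin receptor gene Epha3 (chromosome 16, 63545217 to 63864157) averaged 39.4 ± 32.8 and 155 ± 70.1 (2.20 ± 0.47). Usp42, a deubiquitinase gene, and Arhgef18 had log2 fold changes of 0.69 ± 0.14 and 0.73 ± 0.15. On the lower side stood Phlda1 (chromosome 10, 111506285 to 111508649), with 10468 ± 1950 and 5598 ± 2060 and a log2 fold change of -0.97 ± 0.20. There too stood the neurotrophic factor gene Nenf (-0.78 ± 0.17) and Emd, the gene of the nuclear envelope protein emerin (-0.59 ± 0.13). Each of these 6 higher genes lay above the H3.3WT median in all 7 H3.3K27M tumours, and each of the 3 lower genes below it. The 6 higher genes have exon lengths of 5202 to 20291 bp and the 3 lower genes of 742 to 2517 bp, against a median of 4424 bp over all genes tested, and a slope on exon length differed between the groups (given below). With each library's trend on exon length removed, the log2 fold change was 0.45 ± 0.14 for Kmt2d, 0.52 ± 0.15 for Kmt2c and -0.38 ± 0.13 for Nenf (SE). For the other 6 it was 0.67 for Lig4, 2.02 for Epha3, 0.58 for Usp42, 0.55 for Arhgef18, -0.76 for Phlda1 and -0.43 for Emd.

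**Figure D1:**
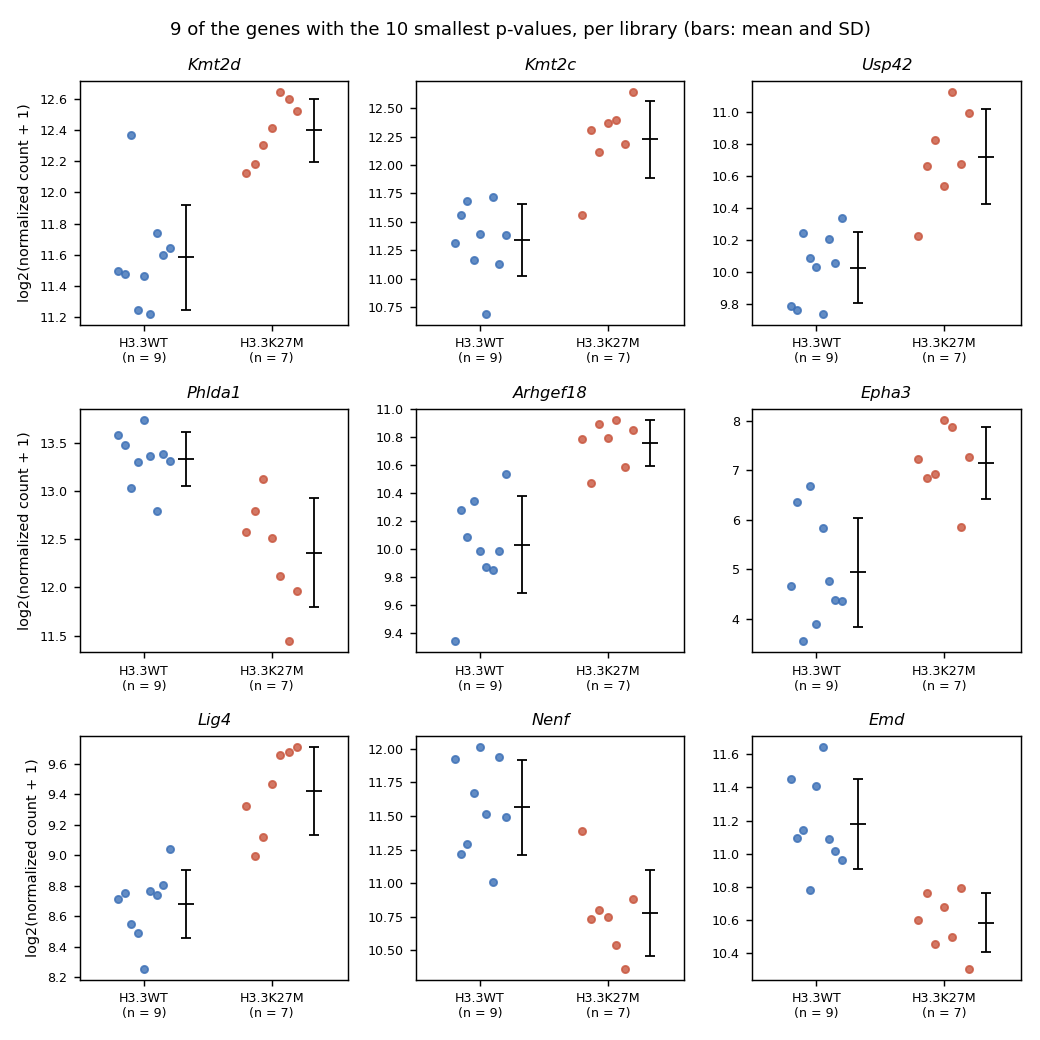
Each point is a library, on a log2(normalized count + 1) axis that does not start at 0, for 9 of the genes with the 10 smallest p-values. Blue points are the 9 H3.3WT and red points the 7 H3.3K27M libraries, bars give mean and SD, and Kmt2d runs from 3155 on average in H3.3WT to 5441 in H3.3K27M tumours with 1 H3.3WT library (library 3) inside the H3.3K27M range.

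None of these differences passed the test across all genes. Of 15007 genes, 0 were higher and 0 lower at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, and Kmt2d and Kmt2c had the smallest adjusted p, 0.256. At an unadjusted p under 0.05 stood 2298 genes (1306 higher, 992 lower), where chance gives 750 on average. As genes vary together, that count spreads widely: 99 other splits of the libraries, described below, gave a median of 568 and up to 3028. edgeR's quasi-likelihood test on the recovered reads called 0 genes and DESeq2's Wald test 112 (67 higher, 45 lower). Leaving out library 10 brought 13 genes past the limma threshold (9 higher, 4 lower), among them Kmt2d, Kmt2c, Usp42, Nenf and Six2, and leaving out library 3 brought Kmt2d past it. The 2298 genes at an unadjusted p under 0.05 became 1493 without library 14, 1288 without libraries 6 and 8, 1384 with each library's trend on exon length removed and 3516 by limma voom with quality weights.

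The authors' deposited table lists 213 genes at an adjusted p under 0.05, of which 123 were higher and 90 lower in H3.3K27M tumours. In the authors' deposited table the adjusted p was 3.3e-04 for Kmt2c, 8.4e-04 for Kmt2d, 5.5e-04 for Lig4 and 0.00699 for Phlda1. Higher genes of the authors' deposited table include Sox6, a transcription factor gene of oligodendrocyte progenitors, and Ptch1, the Hedgehog receptor gene. Lower genes of the authors' deposited table include the chemokine genes Ccl2 and Ccl7, the cytokine gene Il1b, the smooth muscle gene Tagln and the vascular gene Plvap. Of the 213 genes, 211 were tested here, 211 had the same sign, 209 had an unadjusted limma p under 0.05 and 0 passed after adjustment. Both comparisons rest on the same libraries, so the shared signs and small unadjusted p-values are no independent support. The higher genes of the authors' deposited table had a median exon length of 10702 bp and the lower genes 1830 bp, against 4424 bp over all genes tested.

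Inflammatory, mesenchymal and immediate early genes lay lower in H3.3K27M tumours. Of 24 NF-kB and cytokine genes, 22 were lower, with a median log2 fold change of -0.60 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.2e-05, and adjusted p = 0.822 with an estimated correlation). The chemokine gene Ccl7 averaged 265 ± 245 normalized counts (SD, n = 9) in H3.3WT and 38.0 ± 32.3 (SD, n = 7) in H3.3K27M tumours. Ccl2 averaged 1511 ± 1517 and 302 ± 175, and Il1b 282 ± 315 and 62.4 ± 42.6. Of 31 mesenchymal glioma and extracellular matrix genes, 28 were lower (median -0.66, adjusted p = 2.6e-05 by camera, and adjusted p = 0.822 with an estimated correlation). Anxa2, an annexin gene, averaged 5111 ± 2600 and 2148 ± 530, and the intermediate filament gene Vim 26658 ± 12543 and 15976 ± 4349. Of 25 immediate early genes, which respond within minutes to stimuli and to tissue handling, 21 were lower (median -0.79, adjusted p = 2.9e-05 by camera, and adjusted p = 0.822 with an estimated correlation). Junb, a subunit of the AP-1 transcription factor, averaged 6697 ± 5727 and 2401 ± 2327, and Ier3 5706 ± 3126 and 2444 ± 1191; the H3.3K27M mean of Junb was 1575 without library 11. At an unadjusted limma p under 0.05 stood 9, 9 and 7 lower members of these lists, and adjusted over the list alone 0 passed. The blood haemoglobin score, a measure of blood in the tissue, averaged 10.6 ± 3.57 in the H3.3WT (SD, n = 9) and 8.07 ± 2.72 in the H3.3K27M libraries (SD, n = 7; exact permutation p = 0.141).

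Blood, endothelial and neuronal markers lay lower as well. All 5 measured blood haemoglobin genes were lower (median -2.77, camera adjusted p = 0.0214, and adjusted p = 0.822 with an estimated correlation), Hbb-bs averaging 59577 ± 100221 and 5133 ± 8799, a spread larger than the mean in each group. Without library 6 its H3.3WT mean was 28021, and without library 11 its H3.3K27M mean was 1896. All 6 measured neutrophil markers were lower (median -1.10, adjusted p = 0.0310, and adjusted p = 0.822 with an estimated correlation), among them the calgranulin gene S100a8 (127 ± 196 and 19.8 ± 12.9), whose H3.3WT mean was 64.4 without library 6. Of 21 endothelial markers 17 were lower (median -0.41, adjusted p = 0.0201, and adjusted p = 0.823 with an estimated correlation). Plvap, a gene of fenestrated vessels, averaged 992 ± 645 and 319 ± 243 and was the 1 endothelial gene that fell when adjusted over the list alone, whereas the blood-brain barrier transporter gene Slco1a4 averaged 176 ± 162 and 324 ± 132. Of 26 neuron markers 20 were lower (median -0.61, adjusted p = 0.0436, and adjusted p = 0.823 with an estimated correlation), with Thy1 at 1789 ± 1630 and 530 ± 335, the 1 neuron marker that fell when adjusted over the list alone. Gabrb2, a GABA receptor subunit gene of the neuron list, ran the other way at 353 ± 312 and 839 ± 415. Of 70 listed developmental transcription factor genes under Polycomb control 31 were measured, so genes too low to be tested are not covered. Of these 31, 22 were lower (median -0.50, adjusted p = 0.0312, 0.146 with the GC trend removed, and adjusted p = 0.822 with an estimated correlation). Six2 averaged 70.2 ± 37.9 and 19.6 ± 22.7 (H3.3K27M mean 11.3 without library 10) and was the 1 that fell when adjusted over the list alone, and Twist1 averaged 95.2 ± 47.1 and 34.0 ± 29.5. Of 24 replication-dependent histone genes, listed beforehand as a measure of sample handling, 12 were measured. Of these 11 were lower (median -0.55, adjusted p = 0.0195, and adjusted p = 0.822 with an estimated correlation), with the linker histone gene Hist1h1d at 56.3 ± 42.0 and 21.8 ± 15.5. The median exon length was 768 bp for the haemoglobin, 1202.5 bp for the histone and 1871 bp for the neutrophil list, against 4424 bp over all genes tested. With each library's trend on exon length removed, the histone call was lost (median -0.38, adjusted p = 0.111), and the haemoglobin (-2.36, 0.0224) and neutrophil lists (-0.83, 0.0331) passed. Hypoxia and glycolysis genes were lower in 18 of 25 (median -0.29, adjusted p = 0.0436, and adjusted p = 0.823 with an estimated correlation), with the glycolytic gene Pgk1 at 847 ± 457 and 440 ± 102, and complement and coagulation genes in 13 of 17 (median -0.39, adjusted p = 0.0436, and adjusted p = 0.822 with an estimated correlation). Each list of this paragraph lost camera's call in 3 to 9 of the fits that left out 1 library, where the highest adjusted p ran from 0.0743 for the histone to 0.494 for the hypoxia list. The neuron median shrank to -0.24 without library 6 and -0.37 without library 16, and was -0.94, -0.96 and -0.92 without library 7, 13 or 15. The Polycomb median was -0.32, -0.24 and -0.26 without library 4, 12 or 16, the endothelial median -0.22 without library 8 or 15, and the complement median -0.25 without library 14. The hypoxia median was -0.16 and -0.17 without library 2 or 15, and -0.44, -0.47 and -0.50 without library 3, 11 or 16.

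MHC class I, type II interferon response and cell cycle genes lay higher. Of 21 genes of MHC class I and antigen processing, 17 were higher (median log2 fold change 0.59, camera adjusted p = 0.00349, and adjusted p = 0.823 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, averaged 1703 ± 1813 in H3.3WT (SD, n = 9) and 4049 ± 1485 in H3.3K27M tumours (SD, n = 7), and the peptide-trimming gene Erap1 1294 ± 614 and 2100 ± 634. The H3.3WT libraries were unlike each other: Nlrc5 stood at 3389, 3426 and 5207 in libraries 3, 5 and 9 and at 315 to 820 in the other 6. The list score was 12.9, 12.6 and 12.6 in libraries 3, 5 and 9, 10.7 to 11.5 in the other H3.3WT libraries and at least 11.6 in the H3.3K27M libraries. H2-Q6 (3361 ± 4037 and 7146 ± 4273) and H2-Q7 (3407 ± 3635 and 6428 ± 2886) are near-identical genes between which 50 bp reads can be split, so their values are uncertain. Of 18 type II interferon response genes 16 were higher (median 0.77, adjusted p = 0.00349, and adjusted p = 0.823 with an estimated correlation), among them the immunity-related GTPase gene Irgm2 (1444 ± 1630 and 2834 ± 1145). Type I interferon response genes were higher in 19 of 30 (adjusted p = 0.471), and passed camera without library 3 (0.0421) or 15 (0.0409). Of 26 G1/S genes 24 were higher (median 0.32, adjusted p = 7.3e-04, and adjusted p = 0.823 with an estimated correlation), with the histone mRNA-binding gene Slbp at 1103 ± 198 and 1477 ± 287. Of 30 G2/M genes 22 were higher (median 0.21, adjusted p = 0.0214, and adjusted p = 0.823 with an estimated correlation), with the proliferation marker Mki67 at 8059 ± 2575 and 10947 ± 2557. When adjusted over the list alone, 0 members of these lists passed. The type II interferon call was lost without library 12 (adjusted p = 0.0619), the G1/S call without library 3 (0.0602) and the G2/M call without library 3, 4, 11, 15 or 16 (up to 0.428). Without library 3 the median was 0.15 for the G1/S and 0.09 for the G2/M list. The G2/M call was also lost with each library's trend on GC content removed (camera adjusted p = 0.0638).

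**Figure D2:**
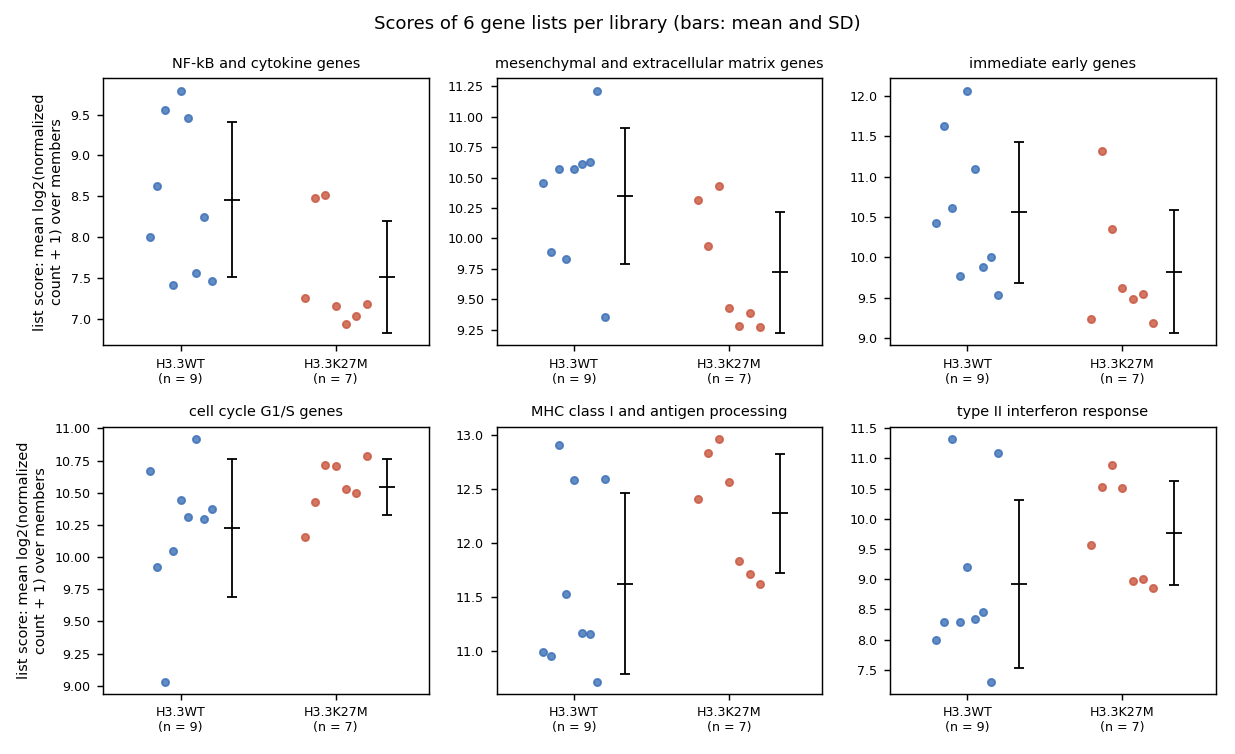
Each point is a library and gives the mean log2(normalized count + 1) over the members of a list, on axes that do not start at 0; blue points are the 9 H3.3WT and red points the 7 H3.3K27M libraries, with mean and SD. The groups overlap in all 6 lists shown, and for the type II interferon response 2 H3.3WT libraries (3 and 9) lie above all 7 H3.3K27M libraries.

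In all, 15 of 41 lists passed camera with its preset correlation of 0.01, and 0 passed with an estimated correlation, by fry in either form, or by an exact permutation test of the list score (smallest adjusted p 0.434 over 11440 assignments). Without library 16, 7 lists passed camera. At an unadjusted exact permutation p under 0.05 stood 4 list scores, those of the INK4 and CIP (p = 0.0170), mesenchymal (p = 0.0369), NF-kB (p = 0.0447) and PRC2 lists (p = 0.0461). The NF-kB, mesenchymal, immediate early and MHC class I lists passed camera in each fit that left out 1 library.

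The lineage and pathway lists below did not pass camera with all 16 libraries. Of 22 oligodendrocyte progenitor markers 16 were higher (camera adjusted p = 0.0613), led by Sox6 (8709 ± 2423 and 15083 ± 4105), the 1 that rose when adjusted over the list alone. This list passed in 6 of the 16 fits that left out 1 library, those without library 1, 2, 4, 5, 12 or 15 (lowest adjusted p = 0.00235), and with the length or GC trend removed, no filter beyond 1 count or edgeR (0.0149 to 0.0442). Pericyte, smooth muscle and fibroblast markers were lower in 16 of 20 (adjusted p = 0.0710), with Tagln at 326 ± 438 and 42.7 ± 19.7. They passed in 5 of the 16, those without library 3, 6, 9, 10 or 13 (lowest adjusted p = 0.0141), and with the length trend removed, edgeR, the neuron score as a covariate or without libraries 6 and 8 (0.0217 to 0.0396). Of the INK4 and CIP cyclin-dependent kinase inhibitor genes, which halt the cell cycle, 5 of 7 were lower (adjusted p = 0.127). Among them Cdkn2a averaged 11847 ± 7016 and 7730 ± 3614 and Cdkn1a 4731 ± 3511 and 2352 ± 2001. SHH pathway genes were higher in 9 of 13 (adjusted p = 0.127, and 0.0494 with the GC trend removed), Ptch1 averaging 1850 ± 466 and 3588 ± 1755. Subunits of PRC2, the complex that writes H3 lysine 27 methylation and that H3.3K27M inhibits, were higher in 8 of 11 (adjusted p = 0.178), Jarid2 averaging 2295 ± 322 and 2667 ± 233. Notch pathway genes were higher in 12 of 18 (0.310), Notch1 averaging 3703 ± 2096 and 6532 ± 1983. Of 39 listed Hox genes 8 were measured, and 7 of these were higher (0.310, and 0.974 without library 6). Glutamate receptor and synapse genes were higher in 18 of 28 (0.444) and MHC class II genes in 9 of 11 (0.547). Microglia and macrophage markers were lower in 17 of 28 (0.189, 0.0257 without library 1 and 0.609 without library 6). Oligodendrocyte and myelin markers were lower in 14 of 22 (0.306, 0.0485 without library 10 and 0.624 without library 6) and ependymal markers in 6 of 7 (0.181, and 0.624 without library 6). p53 target genes were lower in 12 of 22 (0.582) and neural stem and progenitor markers in 13 of 20 (0.597). The ependymal list held 1 gene that fell when adjusted over the list alone, Tm4sf1, and the PDGF and MAPK feedback list (11 of 17 higher, 0.944) held 1, Phlda1. Camera's adjusted p was 0.377 for B cell, 0.385 for BMP and TGF-beta, 0.471 for astrocyte, 0.547 for oncofetal, 0.823 for forebrain, 0.869 for choroid plexus and 0.993 for T and natural killer cell genes. For WNT (0.527), hindbrain and midbrain (0.834) and cerebellar genes (0.876), the median and camera's direction differed in sign.

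The libraries differed in a property that ran along with the groups. The slope of log2 expression on log2 exon length averaged -0.08 ± 0.12 in H3.3WT (SD, n = 9) and 0.10 ± 0.11 in H3.3K27M libraries (SD, n = 7; two-sided exact permutation test, p = 0.00935, adjusted p = 0.0234 over 5 measures). The slope on GC content per 10 points averaged 0.06 ± 0.11 and -0.08 ± 0.06 (p = 0.00717 by the same exact test, adjusted p = 0.0234). Both measures were added after the data were seen. Total reads, genes detected and the share of the 10 most abundant genes had exact permutation p-values of 0.458, 0.612 and 0.588. Library 8 had the lowest length slope, -0.31, and library 6 the highest haemoglobin score, 15.4, and neuron score, 11.4. Labels of 3 H3.3K27M tumours and of 0 H3.3WT tumours start with S21. Labels of 3 H3.3K27M and 8 H3.3WT tumours start with S20, and of 1 tumour of each group with S19. Prefix and group are thus partly confounded, and as no library can be tied to a label, a batch of that kind and the group cannot be told apart. The middle code of the labels, whose meaning is not stated, is shared by more than 1 tumour for 4 codes and 10 tumours. Of these codes, 1 is held by 3 H3.3K27M tumours, 1 by 2 H3.3WT tumours, 1 by 2 H3.3WT and 1 H3.3K27M tumour, and 1 by 1 tumour of each group. All tests here treat the 16 libraries as independent, and no test by code could be made.

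**Figure D3:**
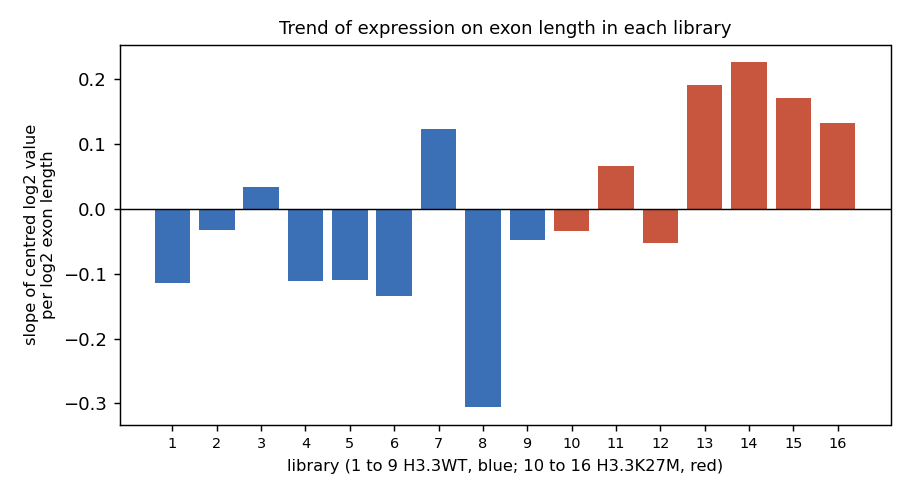
Bars give, for each library, the slope of log2 expression (centred per gene) on log2 exon length over 15005 genes, in log2 units per doubling of length, from a baseline at 0; blue bars are libraries 1 to 9 (H3.3WT) and red bars libraries 10 to 16 (H3.3K27M). Slopes run from -0.31 in library 8 to 0.23 in library 14, with 2 H3.3WT libraries (3 and 7) above 0 and 2 H3.3K27M libraries (10 and 12) below it.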

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

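The patterns weighed below were found in these data, and the tests of them were chosen after the patterns were seen; the slopes on exon length and GC content, the use of an interval to judge the share kept once the length trend was removed, the sets matched on length, the separate reading of blood for NF-kB and mesenchymal genes, and the reading of the T and natural killer cell covariate by how far it moved the medians were chosen after their results were seen. In 128 sets of values (a gene, list score or library measure within a group), 9 had a library far from the others by Dixon's gap-to-range ratio, where chance gives 6.4.

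Library 6 (H3.3WT) had the lowest Hox gene score of its group, 3.20, with the others from 6.66 to 7.86. It also had the lowest score of hindbrain and midbrain transcription factors, 6.56 (others 8.19 to 9.05), and the highest score of ependymal and ciliated cell markers, 9.09 (others 4.70 to 6.39). Library 8 (H3.3WT) held the fewest reads of its group, 11439100 when rounded, and the largest share in its 10 most abundant genes, 5.64% (others 2.17 to 3.26). Library 3 (H3.3WT) had the highest Kmt2d value, 12.36 on the log2 scale (others 11.22 to 11.74), and the highest type I interferon response score, 10.77 (others 8.67 to 9.66). Library 13 (H3.3K27M) had the highest choroid plexus score, 8.77 (others 3.62 to 5.06). Library 15 (H3.3K27M) had the smallest share in its 10 most abundant genes, 2.04% (others 2.63 to 3.05).

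Long transcripts lay higher and short transcripts lower in H3.3K27M tumours: 115 of 123 higher calls of the authors' deposited table were longer than the median gene tested and 80 of 88 lower calls shorter. With each library's trend on GC content removed, 97.2% of 211 calls kept an unadjusted limma p under 0.05. The calls were chosen for small p in these same libraries, so that share alone decides little. Their median log2 fold change in the called direction went from 0.74 (median SE 0.20) to 0.67 (0.20). The medians argue against a GC trend as the whole cause of the calls, but whether the length order stayed was not tested. Library 8 is argued against as the whole cause of the length slope, which still differed without it (two-sided exact permutation p = 0.0166). A feature of H3.3K27M tumours alone stays open: among the 9 H3.3WT libraries the difference between higher and lower calls followed the length slope of the other genes (Pearson r = 0.88, exact permutation p = 0.00151, adjusted p = 0.00406 over 4 relations; Spearman rho = 0.90, p = 0.00203; r = 0.69 without libraries 7 and 8), but 1000 sets of other genes matched on exon length gave a median r of 0.95 (central 95% 0.86 to 0.99), so that r decides nothing. With the length trend removed, 80.6% of the calls (95% Wilson interval 74.7 to 85.3) kept an unadjusted p under 0.05, while their median log2 fold change in the called direction went from 0.74 (median SE 0.20) to 0.51 (0.17) and the genes at that p went from 2298 to 1384. The interval counts the calls as independent, though they come from the same libraries and varied together, so it does not measure the spread between tumours. Even this interval spans the bound of 80% set beforehand. A length trend, such as RNA quality or library preparation could bring, and an effect of H3.3K27M on these genes therefore cannot be told apart.

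Cytokine, immediate early and mesenchymal genes lay lower in H3.3K27M tumours. As the whole cause, a trend on transcript length and libraries 6 and 8 are argued against by the medians. The NF-kB, mesenchymal and immediate early medians went from -0.60, -0.66 and -0.79 to -0.52, -0.69 and -0.62 with the length trend removed. Without libraries 6 and 8 they were -0.49, -0.48 and -0.70. In both fits 3 of 3 lists kept a camera adjusted p under 0.05, a call that alone decides little, as other splits of the libraries passed a median of 12 lists. With the haemoglobin score as a covariate 3 of 3 kept it too, but the immediate early median went from -0.79 to -0.36 (adjusted p = 0.0224), so for that list blood left in the tissue stays open. For NF-kB (-0.60 to -0.40, camera adjusted p = 9.0e-04) and mesenchymal genes (-0.66 to -0.50, 6.8e-04) most of each median stayed and 2 of 2 kept the call. For these 2 lists blood is argued against as the whole cause only as far as the haemoglobin score measures it, and it may account for part. An effect of H3.3K27M stays open, as do tumour stage and tissue handling, which were not tested, and these calls rest on camera's preset correlation.

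MHC class I and type II interferon genes lay higher in H3.3K27M tumours. As the whole cause, the shallow library 8 is argued against, because the medians went from 0.59 to 0.47 and from 0.77 to 0.61 without it. In that fit 2 of 2 lists kept a camera adjusted p under 0.05 (adjusted p = 0.0106 and 0.0152). With the T and natural killer cell score as a covariate 2 of 2 kept it too, but the medians barely moved (0.59 to 0.55 and 0.77 to 0.73). T and natural killer cell content therefore stays open, since the score rests on 16 markers near the floor, with a median of 15.1 normalized counts, and averaged 4.07 in H3.3WT and 4.13 in H3.3K27M libraries. An effect of H3.3K27M stays open and rests, as above, on camera's preset correlation.

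The 16 libraries were split into 9 and 7 in 100 ways, the real one included. At an unadjusted limma p under 0.05, 3 splits, the real one among them, gave at least the real 2298 genes (highest other 3028). That share is under 0.05 and argues against chance for the gene count. It was not adjusted over the 3 counts tested in this way, so chance is not excluded. As many lists past camera's threshold as the real 15 came from 29 of 100 splits (highest other 21), so chance is not excluded for the list count. With DESeq2 on the recovered reads, 6 of 21 splits gave as many genes as the real 112, so chance is not excluded there either. The highest other split gave 1640, several times the real count, which points to a structure of the samples other than the groups. Its group of 7 held libraries 2, 4, 5, 6, 8, 10 and 12, which all had a negative length slope. Every library with a positive length slope lay in its other group, together with libraries 1 and 9. That split thus ran along the length slope given above, and other properties were not compared. It is 1 split, the next highest gave 186, and no split by slope was tested.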

How the results depend on the processing

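The edgeR test, both other pseudocounts, the length and GC corrections and the fit without libraries 6 and 8 were chosen after the data were seen. By limma 0 genes were higher and 0 lower (2298 at an unadjusted p under 0.05; 1493 to 2896 when 1 library was left out, lowest without library 14, 1288 without libraries 6 and 8, 1384 with the length trend removed and 3516 with voom), and both counts stayed at 0 under TMM and upper quartile scaling, both other filters, all 3 covariates, and the settings added later. DESeq2's Wald test on the recovered reads gave 67 higher and 45 lower genes, 104 of the 112 also called in the authors' deposited table, and voom with quality weights gave 2 higher genes, Kmt2d and Kmt2c; the cause was not tested. Leaving out 1 library gave 0 to 9 higher and 0 to 4 lower genes: 9 and 4 without library 10, 1 higher without library 3.

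The count of lists past the threshold, 15, became 9 with at least 1 CPM in at least 7 libraries, 9 with voom with quality weights, 0 with camera's estimated correlation, 0 by fry and 0 by the exact permutation test; the cause was not tested. Other settings gave 11 to 17. Leaving out 1 library gave 7 to 16 lists, 7 without library 16. Calls were lost for the G1/S list without library 3 (adjusted p = 0.0602), the type II interferon list without library 12 (0.0619), the histone list without library 6, 9 or 16 (up to 0.0743), the endothelial list without library 4, 7, 15 or 16 (up to 0.0815), the haemoglobin list without library 2, 6, 7 or 16 (up to 0.0749) and the G2/M list without library 3, 4, 11, 15 or 16 (up to 0.428). They were lost for the Polycomb list without library 1, 3, 4, 7, 12 or 16 (up to 0.242), the hypoxia list without library 1, 2, 6, 10, 12, 14 or 15 (up to 0.494), the neutrophil list without library 3, 5, 6, 7, 8, 14 or 16 (up to 0.0995), the complement list without library 2, 3, 6, 7, 8, 11, 14, 15 or 16 (up to 0.127) and the neuron list without library 3, 4, 6, 9, 10, 11, 12, 14 or 16 (up to 0.277). With the length trend removed the histone list lost its call (adjusted p = 0.111). Removing the GC trend lost the Polycomb (camera adjusted p = 0.146) and G2/M calls (0.0638). TMM and upper quartile scaling lost the neuron, hypoxia and complement calls (0.0509 to 0.0609). The fit without libraries 6 and 8 lost the haemoglobin (0.0901), neutrophil (0.194), hypoxia (0.230) and complement calls (0.0901). Voom, both other filters and the covariates lost calls as well. Calls were gained when 1 library was left out for the oligodendrocyte progenitor (6 of 16 fits), pericyte (5), type I interferon (2), microglia (1) and myelin lists (1), and under other settings for the progenitor, pericyte and SHH lists. Without libraries 6 and 8 together 12 lists passed. By list score 0 lists differed under each setting run. The median of all genes stayed between -0.03 and 0.02. Of 5440 comparisons of a named gene with its value under another setting, 3 changed sign with neither value called. Of 1227 for lists, 67 did. Both totals include called genes and lists, so the shares among uncalled ones are higher.

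No paired analysis was possible because the columns carry no replicate numbers of the labels. For the same reason the fits by label prefix were not run, and the mitochondrial covariate was not run as those genes were not analysed here. Depth limits low genes most in library 8, where 3 reads are 8.52 normalized counts.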

Other observations

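All tests of gene families in this part were chosen after the result was seen. Subunits of mitochondrial complex I, the first enzyme of the respiratory chain, lay lower in H3.3K27M tumours in 36 of 37 measured genes (median log2 fold change -0.49), 8 of them among the lower genes of the authors' deposited table. Subunits of cytochrome c oxidase were lower in 14 of 16 (median -0.46), of ATP synthase in 14 of 17 (-0.31) and cytosolic ribosomal proteins in 75 of 78 (-0.35). Lysine methyltransferase genes of the Kmt2, Setd, Nsd and Ash1l families were higher in 12 of 15 (median 0.47), chromodomain helicase genes in 8 of 9 (0.32), lysine acetyltransferase genes in 8 of 10 (0.16) and SWI/SNF subunit genes in 11 of 17 (0.13). The families were picked after the genes with the smallest p-values and the authors' calls were seen, so these counts describe the families and are no test that they differ.

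These families are short or long as a class, complex I genes having a median exon length of 1495 bp and the methyltransferases 10813 bp, so each median was set against 10000 random lists matched on exon length and expression. The percentiles were 0.01 for complex I, 0.46 for ribosomal proteins, 8.91 for cytochrome c oxidase, 8.91 for ATP synthase, 33.9 for SWI/SNF subunits, 65 for acetyltransferases, 71.1 for chromodomain helicases and 99.7 for methyltransferases, and since the families were picked after the results were seen and members of a family can vary together, they decide no cause. With the length trend removed the median was -0.13 for complex I, -0.16 for cytochrome c oxidase, -0.11 for ATP synthase, -0.13 for ribosomal proteins, 0.20 for methyltransferases, 0.09 for chromodomain helicases, 0.16 for acetyltransferases and -0.00037 for SWI/SNF subunits. Length and a shift of the family cannot be told apart for the 3 families outside the central 95% of matched lists. Complex I and the methyltransferases hold 8 and 5 calls of the authors' deposited table, the kind of gene for which families were picked, so their scores with the length trend removed (exact permutation p = 0.0216 and 0.00140) decide nothing, and the ribosomal protein score did not pass (p = 0.389 by the same exact test).

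Library 8 had Mir6236 as its most abundant gene, with 2.08% of its reads. Of the 634 genes whose overall mean in the authors' deposited table lies below the plain mean of the libraries, library 6 held the highest value for 300.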
